A study of Mus musculus with 12 samples.

How the data were processed

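The study measured poly(A) RNA in livers of C57BL/6 mice by sequencing. Mice were wild type or carried a liver-specific knockout of Atf4, the gene of a transcription factor that cells make during endoplasmic reticulum (ER) stress. They received 1 mg/kg tunicamycin, which blocks N-linked glycosylation and so causes ER stress, or 0.3% DMSO, the solvent, by intraperitoneal injection, and livers were taken 6 h later. Per the labels' protocols, livers were flash frozen, RNA was extracted with TRIzol, and ERCC spike-in RNA was added before TruSeq library preparation. The labels give 12 libraries in 4 groups of 3: wild type with DMSO, wild type with tunicamycin, knockout with DMSO and knockout with tunicamycin. No label pairs libraries across groups. Per the labels, the 3 knockout DMSO libraries were sequenced on lane 5 and the other 9 on lane 4, so lane and group cannot be told apart in either comparison that uses the knockout DMSO group. In both remaining comparisons of groups all libraries share lane 4.

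Per the submitters' processing notes, reads were converted with bcl2fastq, aligned with TopHat2 2.0.4 to the mouse build mm9, and assembled and compared with Cufflinks and Cuffdiff. The annotation, the filters and the normalization between libraries are not given in the sources used here. The authors' deposited table is Cuffdiff's table of loci, and per the file headers its values are 1 FPKM (fragments scaled to transcript length and to all mapped fragments) per locus and group, with the 3 libraries of a group pooled. For each of 6 comparisons of groups the authors deposited a log2 fold change, a test statistic, a p-value and a q-value per locus. The values per library and the read counts behind them were not used here, so no SD, no library left out, no other split of the libraries and no interval can be given, and the depth of each library is unknown. The pooling also hides whether 1 library carries a group's value.

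The table holds 27109 loci, of which 23951 carry a gene name and 3158 (11.6%) do not. A further property of the assembly is that 457 loci carry the names of several genes merged into 1 locus, and that 643 symbols stand at more than 1 locus. For such a symbol the locus of that name alone with the highest mean FPKM was used. A few names had been turned into dates by a spreadsheet and were left as they stood. Cells that read #NAME? stand for a fold of minus infinity. For tested loci with at least 1 FPKM in both groups the deposited log2 fold change equalled the log2 ratio of the deposited FPKM within 1.29e-05. The smallest deposited p-value is 5e-05 and the smallest q-value 0.000396. The deposited q-values equalled a Benjamini-Hochberg adjustment over the 90828 tests of all 6 comparisons together, within 5.29e-07, so the number of calls in 1 comparison depends on the others. Locus positions are given in mm9 as in the table.

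Tests for values per library and for group values had been laid down in advance, and the one for group values with the authors' own test applied. A locus was called when its deposited q was under 0.05 and its test status was OK, with the direction of the deposited log2 fold change, and this rule was written before the data were examined. The words rose, fell, higher and lower refer to such calls. The 4 comparisons used were knockout against wild type under DMSO, tunicamycin against DMSO in wild type, tunicamycin against DMSO in the knockout, and knockout against wild type under tunicamycin. Both crossed comparisons, in which genotype and treatment differ together, were not used. The computations ran in Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.

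Before the data were examined, 34 lists of 530 genes were fixed for pathways of the liver and of the stress response and for markers of cell types, and 526 of the genes matched a locus. For each list and comparison the called members were counted with the deposited q and, in a second count, with p-values adjusted over the list alone. Fisher's exact test (two-sided) set called against other tested named loci, for rises and falls separately, and its p-values were adjusted by Benjamini-Hochberg over lists and directions within a comparison. The median log2 fold change of a list was also placed among 10000 random lists of the same size matched on mean FPKM in 20 bins, as a description. After the data were seen, 8 further lists were written for other tissues and for targets of the tumour suppressor p53. Another 37 markers of adrenal cortex, adrenal medulla, muscle and fat were picked after that, before their own values were looked at, to test whether RNA of these tissues was present.

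The difference between both tunicamycin responses was tested for the 14510 loci with a finite fold change and a test in both genotypes. The standard error of each deposited log2 fold change was taken as its size divided by the scaled test statistic, with 1 scale per comparison set by the deposited p-values (1.73 in each tunicamycin comparison). The cut for checking them was the largest deposited p-value among called loci. The scaled statistics fell on the same side of it as the deposited p-values at 97.4% of loci in wild type and 97.3% in the knockout. The knockout response minus the wild-type response was divided by its standard error, and two-sided normal p-values were adjusted over all loci, with calls under 0.05. This test is approximate: at loci whose deposited statistic is stronger than their deposited p-value it makes calls that the p-values alone would not.

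The difference test was tested on simulated data, in 20 draws of 14510 loci with 201 changed. With the spread of the deposited table it recovered 23.1%, 72.9% and 91.2% of loci with log2 differences of 1, 2 and 4, and 5.11% of its calls were at unchanged loci. A wider spread, tried first, gave 2.91%, 34.6% and 93.5%, with 4.36% of calls at unchanged loci. The simulations take the spread as known and tie statistic and p-value by a fixed scale. In the deposited table statistic and p-value differ at some loci, as stated above. The simulated shares therefore describe the method under these assumptions. They cannot give the share of false calls, or of changes missed, in the deposited table. In the simulated list tests a planted list gave a Fisher's exact p of 4.37e-16, and 1 of 50 unchanged lists had p under 0.05. Unchanged lists and calls were drawn independently there. These values therefore do not show how the list p-values behave for genes that move together.

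Genes were named by a rule written before the data were examined. In each comparison it took Atf4, the 6 largest rises and 6 largest falls among called loci with at least 5 FPKM in the higher group and above 0 in the lower, and then up to 2 called members with at least 1 FPKM from the lists with the most calls, until about 30 genes were reached. For the difference it took the 6 largest on each side with at least 5 FPKM in any group. Other members of a list are named only as parts of that list. A few genes picked by the rule are not reported here. Reads of Cyp, Serpina, Saa, Mup, Hamp, Hbb, Slc22a and similar families are shared between near-identical copies, so the value of 1 copy is uncertain.

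The alternatives fixed in advance were q under 0.01, a log2 fold change of at least 1, means of at least 1 and 5 FPKM, a pseudocount of 1 FPKM, adjustment within each comparison alone, centring on the median locus, and leaving out multigene families. Several were added after the data were seen: leaving out loci at least 5 times higher in the knockout tunicamycin group than in each other group, other standard errors for the difference test, and gene lists with calls adjusted within each comparison. Spike-in RNA was not analysed here. Hspa5 and Hsp90b1, the main ER chaperones, have the status of too much data in both tunicamycin groups and are listed at 0 there, so they could not be assessed, and Alb was listed at 0 in all 4 groups for the same reason. Hmgcs1, of cholesterol synthesis, stands only at loci with 0 FPKM and had no test.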

Results

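Livers of wild-type mice and of mice with a liver-specific knockout of Atf4 were compared 6 h after tunicamycin or DMSO, with 3 libraries in each of 4 groups. Loci at or above 1 FPKM in the authors' deposited table numbered 12326 in wild type with DMSO, 12135 in wild type with tunicamycin, 12484 in the knockout with DMSO and 12468 in the knockout with tunicamycin. The 10 most abundant loci held 15.1%, 11.4%, 12.9% and 10.7% of the summed FPKM in the same order. Loci with at least 1 FPKM that were 5 or more times higher in 1 group than in each other group numbered 14, 16, 6 and 184. The 184 of the knockout tunicamycin group include genes of adrenal gland, skeletal muscle and fat, which are described with the comparison they enter most.

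Atf4 itself lies in a locus that the assembly merged with the calcium channel gene Cacna1i (chromosome 15, 80085614 to 80228829). The authors' deposited table gives this locus 46.9 FPKM in wild type and 22.8 in the knockout with DMSO, and 356 and 114 with tunicamycin. Knockout against wild type was -1.04 on the log2 scale with DMSO (q 0.270, not called) and -1.64 with tunicamycin, a fall, both in the authors' deposited table. With tunicamycin the locus rose by 2.92 in wild type (q 0.0227) and by 2.32 in the knockout, per the authors' deposited table. Which exons were deleted is not given in the sources used here, and the value counts reads of the whole merged locus in all cells of the liver, so it does not measure how complete the deletion was. Rps19bp1, at the same mapped interval, read 13.0 and 1.91 FPKM with DMSO and 23.6 and 3.94 with tunicamycin in wild type and knockout in the authors' deposited table, and was not called in any of the 4 comparisons.

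Without stress, knockout livers had higher transcripts of liver endothelium and of stellate cells, the perivascular cells that make collagen, and higher targets of the tumour suppressor p53, while no ER chaperone was called. Lane and genotype cannot be told apart in this comparison. The scavenger receptor Stab1 of sinusoidal endothelium rose by 1.00 on the log2 scale and the VEGF receptor Kdr by 0.95, in the authors' deposited table. Smooth-muscle actin Acta2 (1.97) and collagen Col1a1 (0.81) were higher too, as were the cell-cycle inhibitor Cdkn1a (1.47) and the death receptor Tnfrsf10b (1.35), per the authors' deposited table. Of 14788 tested loci 423 were called in the authors' deposited table, 206 higher and 217 lower. At least 2-fold changes were 58 up and 47 down, and 1055 loci had an unadjusted p under 0.05. With q computed within this comparison alone 105 calls were left.

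Among called loci with at least 5 FPKM in the higher group, the largest rises were Dancr with Snora26, a noncoding RNA locus (4.08 to 38.4 FPKM, log2 3.23), and the leukocyte adhesion receptor Cd97 (3.99-fold, to 29.9 FPKM), in the authors' deposited table. They were followed in that set by Serpina4-ps1, a serpin pseudogene (1.83), the transcription factor gene Zbtb16 (1.67), the uncharacterised 1700061I17Rik (1.54) and Cox6b2, a testis form of a cytochrome oxidase subunit (1.52; all from the authors' deposited table). The largest falls of that set in the authors' deposited table were the uncharacterised 2210011C24Rik (-5.80), the host of the myeloid microRNA Mir223 (-4.65), the cytochrome P450 genes Cyp2c39 (-4.41) and Cyp3a16 (-4.15), Mir365-2 (-3.53) and the let-7 locus Mirlet7a-1 (-3.41). With q within this comparison the calls of Cox6b2 and 2210011C24Rik ended, as did those of hepcidin, Tnfrsf10b, Atf3, Baat, Fasn, Cyp4a14 and the Cyp4a10 locus, which are described with their lists.

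Endothelial markers had the smallest p of the lists fixed before the data were examined: 8 of 11 were higher, 10 adjusted over the list alone, with a median log2 change of 0.73 (Fisher's exact test, two-sided, p 5.27e-13, adjusted 3.58e-11). Cdh5, the cadherin of endothelial junctions, rose by 0.76 and the angiopoietin receptor Tek by 0.69 in the authors' deposited table. Stellate cell and fibroblast markers were higher at 4 of 11, also 4 over the list alone (p 1.82e-05, adjusted 0.000412, Fisher's exact test), and the others, such as Lrat, which stores vitamin A (0.07 in the authors' deposited table), did not pass. Macrophage markers had 0 of 13 called by Cuffdiff, and 2 had an unadjusted p under 0.05. Their median of 0.02 stood at percentile 97.6 of random lists, so they leaned higher, by far less than the endothelial markers. When q was computed within this comparison alone, 3 of 11 endothelial markers (Fisher's exact p 9.16e-06, adjusted 0.000623) and 2 of 11 stellate markers (0.000811, adjusted 0.0276) were still higher. All 3 knockout DMSO libraries ran on a lane of their own, so this whole comparison cannot separate genotype from lane.

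Cell death and p53 genes were higher at 5 of 13 and at 6 adjusted over the list alone (Fisher's exact p 1.08e-06, adjusted 3.66e-05): besides Cdkn1a and Tnfrsf10b these were the apoptosis effector Bax (0.63), the p53 ubiquitin ligase Mdm2 (0.59) and cyclin G1, Ccng1 (0.57), in the authors' deposited table. Under q within this comparison the adjusted p of this list was 0.535. Fatty acid synthesis had 3 of 17 higher, 3 over the list alone (Fisher's exact p 0.00223, adjusted 0.0304): the lipase-related Pnpla3 (1.75), fatty acid synthase Fasn (0.84) and Aacs (0.67) in the authors' deposited table. Bile acid genes were lower at 3 of 14, 1 over the list alone (Fisher's exact p 0.0012, adjusted 0.0204), with the oxysterol hydroxylase Cyp39a1 at -0.81 and the conjugating enzyme Baat at -0.63 in the authors' deposited table. Fatty acid oxidation was lower at 3 of 19, 0 over the list alone (Fisher's exact p 0.00302, adjusted 0.0307), among them Cyp4a14 (-0.74) and the merged Cyp4a10 locus (-0.62) of the authors' deposited table. Acute phase genes went both ways, 3 higher and 3 lower of 20 in both counts (Fisher's exact p 0.00361 and 0.00351, adjusted 0.0307 each): Saa1 rose from 133 to 273 FPKM (1.04) and hepcidin, Hamp with Hamp2, fell from 4444 to 2167 (-1.04), in the authors' deposited table. With q taken within this comparison these calls ended as well (adjusted p 0.535 for fatty acid synthesis and for bile acids, 1 for fatty acid oxidation, 0.0621 and 1 for acute phase rises and falls, all Fisher's exact tests).

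Few of the stress genes that ATF4 is known to drive were called without stress. Of 23 ATF4 and CHOP targets 2 were lower, the stress factors Atf3 (-1.29) and Atf5 (-1.13), and 1 was higher, Tnfrsf10b, in the authors' deposited table (adjusted over the list alone the counts were the same; adjusted Fisher's exact p 0.281 for falls). The list as a whole leaned lower, with a median of -0.30 at percentile 0.155 of random lists, and 5 of 23 were lower at an unadjusted p under 0.05, by the authors' deposited table. Cuffdiff called 0 of 13 genes of amino acid synthesis, 0 of 11 amino acid transporters, 0 of 20 cytosolic tRNA synthetases, 0 of 17 ER chaperones and 0 of 18 genes of ER-associated degradation, of which 2, 0, 1, 0 and 0 had an unadjusted p under 0.05. In the secretory list 1 of 22 was lower, the co-chaperone Dnajb9 (-0.89 in the authors' deposited table). Cholesterol biosynthesis had 0 of 19 called by Cuffdiff, with 2 at an unadjusted p under 0.05, but its median of 0.10 stood at percentile 100 of random lists. Cholesterol uptake had 1 of 11 higher (Mylip, a ubiquitin ligase, 0.63) and export 1 of 19 lower (apolipoprotein Apoc2, -0.61), per the authors' deposited table. The export list leaned lower, with a median of -0.40 at percentile 0.02, and 5 were lower and 1 higher at an unadjusted p under 0.05. Among growth hormone and sex-biased genes A1bg rose by 1.13 and the signalling inhibitor Socs2 changed by -0.94 in the authors' deposited table, with 1 higher and 2 lower of 20 (adjusted Fisher's exact p 0.975 and 0.261).

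Tunicamycin in wild type moved 37.1% of tested loci. Genes of the stress response were among the largest rises: CHOP (Ddit3) went from 15.2 to 2385 FPKM and the ER-associated degradation gene Derl3 from 2.74 to 737, in the authors' deposited table. Enzymes of fatty acid oxidation, bile acid synthesis and drug metabolism, which make up much of a hepatocyte's own work, fell. Cholesterol genes went both ways, with mevalonate diphosphate decarboxylase Mvd up by 2.41 and the sterol exporter Abcg8 down (-2.20) in the authors' deposited table. Calls in the authors' deposited table numbered 5566 of 14998, 2709 higher and 2857 lower, of which 1676 and 1696 were at least 2-fold. At an unadjusted p under 0.05 there were 7005.

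With at least 5 FPKM in the higher group, the largest called rises in the authors' deposited table were Derl3 (log2 8.07), the predicted gene Gm6614 (7.60), the serine synthesis enzyme Psat1 (7.55), the stress regulator Nupr1 (7.53), Ddit3 (7.29) and Atf3 (7.26). The largest falls by the same limit were 2210011C24Rik (-6.53), the acyl-CoA thioesterase Acot3 (-6.01), endothelial lipase Lipg (-5.71), Cyp2c39 (-5.12), the noncoding C730036E19Rik (-4.91) and the membrane protein gene Tmem25 (-4.88), by the authors' deposited table.

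Several lists of the response to unfolded proteins rose. Of 23 ATF4 and CHOP targets 18 were higher in both counts (Fisher's exact p 2.03e-09, adjusted 3.45e-08), for example the pseudokinase Trib3 (6.00) and the hormone Fgf21 (4.84) of the authors' deposited table. ER chaperones were higher at 13 of 15, also 13 adjusted over the list alone (median 2.82; Fisher's exact p 4.21e-08, adjusted 4.77e-07), with Creld2 at 6.17 and Sdf2l1 at 4.51 in the authors' deposited table. ER-associated degradation was higher at 16 of 18 in both counts (Fisher's exact p 4.5e-10, adjusted 1.02e-08; the ubiquitin ligase Syvn1 4.58 in the authors' deposited table). Secretory genes rose at 19 of 22, 20 over the list alone (p 2.7e-11, adjusted 9.19e-10, Fisher's exact), with Dnajb9 (3.60) and the signal recognition receptor Srprb (2.29) in the authors' deposited table. Cytosolic tRNA synthetases were higher at 18 of 20 in both counts (p 2.11e-11, adjusted 9.19e-10, Fisher's exact), led by Wars (2.71) and Iars (2.23) of the authors' deposited table. Of 17 sensors and regulators 8 were higher in both counts (adjusted Fisher's exact p 0.0461, and 0.0572 with q within this comparison), among them the ER stress sensor PERK, Eif2ak3 (2.64 in the authors' deposited table). Amino acid synthesis, with 7 higher and 4 lower of 18, and transporters, with 6 higher and 3 lower of 13, did not pass as lists (adjusted Fisher's exact p 0.172 and 0.0967 for rises), although Aldh18a1 of proline synthesis (6.14) and the arginine carrier Slc7a1 (6.07) were among the large rises of the authors' deposited table. The transporter list passed with q within this comparison (adjusted Fisher's exact p 0.0111).

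Most metabolic lists had more falls than rises. Fatty acid oxidation was lower at 16 of 19, 17 over the list alone (Fisher's exact p 5.26e-09, adjusted 7.16e-08), with the master regulator Ppara at -2.07, and the 1 higher member was the kinase Pdk4, which spares glucose (3.06), in the authors' deposited table. Drug-metabolising P450 genes were lower at 11 of 16, 12 over the list alone (Fisher's exact p 4.36e-05, adjusted 0.000371; Cyp3a25 -1.46), while Cyp2b10 rose by 2.43, both from the authors' deposited table. Gluconeogenesis and glycogen were lower at 8 of 12 in both counts (Fisher's exact p 0.000719, adjusted 0.00489), with Pck1, its rate-setting enzyme, at -3.63 in the authors' deposited table. Growth hormone and sex-biased genes were lower at 12 of 20 in both counts (p 0.000137, adjusted 0.00104, Fisher's exact), such as Igfals, the carrier of circulating IGF1 (-4.11), and the female-biased factor Cux2 (-3.56) of the authors' deposited table. Acute phase genes were lower at 10 of 20, 11 over the list alone (p 0.00327, adjusted 0.0171, Fisher's exact), with haptoglobin, Hp, at -1.75 in the authors' deposited table. Fatty acid synthesis had 6 lower and 2 higher of 16, 7 and 2 over the list alone, and did not pass (adjusted Fisher's exact p 0.274 for falls).

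Genes of cholesterol handling were mostly lower. Biosynthesis had 10 of 19 lower and 3 higher, 10 and 4 over the list alone (Fisher's exact p for falls 0.002, adjusted 0.0124): Dhcr7 (-1.31) and Idi1 (-0.93) were lower, and Fdps (1.51) and Lss (1.09) higher with Mvd, in the authors' deposited table. Export and lipoprotein genes were lower at 13 of 19 in both counts (Fisher's exact p 9.13e-06, adjusted 8.87e-05), such as apolipoprotein Apoa5 (-2.46) and Abcg5 (-1.88) of the authors' deposited table. Uptake and sensing had 5 lower and 3 higher of 11 in both counts and did not pass (adjusted Fisher's exact p 0.154 for falls): the sterol sensor gene Insig1 was at -1.77 and the lysosomal cholesterol exporter Npc1 at 2.70 in the authors' deposited table. Bile acid genes were lower at 8 of 14, 9 over the list alone (p 0.00293, adjusted 0.0166, Fisher's exact), with Cyp7a1, the first enzyme of the classic route, going from 105 to 13.8 FPKM (-2.93) in the authors' deposited table.

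In the knockout the ER arms of the response rose too, and transcripts of muscle and adrenal gland stood among the largest rises. CHOP (Ddit3) reached 2066 FPKM and Atf3 went from 1.06 to 261, in the authors' deposited table. ER chaperones were again higher at 13 of 15 and ER-associated degradation at 16 of 18, while cholesterol, bile acid and fatty acid genes fell. Called loci in the authors' deposited table were 5121 of 15534, 2816 higher and 2305 lower, of which 1713 and 1294 were at least 2-fold. An unadjusted p under 0.05 was found for 6611. The knockout DMSO group ran on a lane of its own, so lane and tunicamycin cannot be separated at a single locus here. At loci tested in both genotypes, 2121 of 2611 rises and 1951 of 2268 falls were called alike in wild type, within 1 lane (477 and 440 expected). These values argue against lane as the cause of the whole response.

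The muscle myosins Myh1 (log2 8.31) and Myh2 (8.13), the adrenal reductase Akr1b7 (8.12), Atf3 (7.94), fast-muscle troponin Tnni2 (7.92) and Ddit3 (7.69) rose most among called loci with at least 5 FPKM in the higher group of the authors' deposited table. The largest falls within that limit were Lipg (-5.45), C730036E19Rik (-5.05), Acot3 (-4.68), the hepatocyte transcription factor Onecut1 (-4.29), the kinase Dclk3 (-4.27) and Tmem25 (-4.26), by the authors' deposited table. Of the loci higher here, 96 belong to the 184 that stood 5 or more times above each other group, and 5025 calls were left without those (2720 higher and 2305 lower).

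ATF4 and CHOP targets were higher at 17 of 23, 18 adjusted over the list alone (median 1.51; Fisher's exact p 3.39e-08, adjusted 5.76e-07), with Trib3 at 6.10 and Fgf21 at 4.85 in the authors' deposited table. ER chaperones (13 over the list alone; median 2.41; Fisher's exact p 5.26e-08, adjusted 7.15e-07) included Creld2 at 5.46 and Sdf2l1 at 4.21 in the authors' deposited table. ER-associated degradation (16 over the list alone; Fisher's exact p 5.93e-10, adjusted 4.04e-08) included Derl3 at 7.25 and Syvn1 at 4.26 in the authors' deposited table. Secretory genes were higher at 17 of 22, 18 over the list alone (p 1.09e-08, adjusted 2.82e-07, Fisher's exact; Dnajb9 4.13 and Srprb 2.39 in the authors' deposited table). The tRNA synthetases were higher at 16 of 20, 17 over the list alone (p 1.24e-08, adjusted 2.82e-07, Fisher's exact; Wars 2.08 and Sars 1.68 in the authors' deposited table). Sensors and regulators were higher at 8 of 17 in both counts (p 0.0106, adjusted 0.0379, Fisher's exact). Amino acid synthesis had 5 higher and 6 lower of 18 and transporters 4 higher and 3 lower of 12, and neither passed (adjusted Fisher's exact p 0.602 and 0.488 for rises).

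Several metabolic lists fell in the knockout as well. Fatty acid oxidation was lower at 13 of 19, 14 over the list alone (Fisher's exact p 4.02e-07, adjusted 3.42e-06), with Ppara at -2.14 and Pdk4 again higher at 2.58 in the authors' deposited table. Fatty acid synthesis, which had not passed in wild type, was lower at 10 of 17 in both counts (Fisher's exact p 6.45e-05, adjusted 0.000337), with its regulator Srebf1 at -2.69 and the thyroid-responsive Thrsp at -2.07 in the authors' deposited table. Drug-metabolising P450 genes were lower at 12 of 16 in both counts (p 2.36e-07, adjusted 2.67e-06, Fisher's exact; Cyp3a25 -1.77 in the authors' deposited table), and Cyp2b10 rose by 2.57 in the authors' deposited table. Gluconeogenesis was lower at 9 of 12 in both counts (p 8.59e-06, adjusted 5.39e-05, Fisher's exact; Pck1 -3.40 in the authors' deposited table). Growth hormone genes were lower at 12 of 20 in both counts and acute phase genes at 12 of 20 in both counts (p 8.72e-06, adjusted 5.39e-05 each, Fisher's exact), with the cytokine-signal inhibitor Socs3 at -2.52 and hepcidin higher at 2.37 in the authors' deposited table.

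Cholesterol biosynthesis was lower at 9 of 19 in both counts (Fisher's exact p 0.00125, adjusted 0.00567), with Idi1 at -0.70 and Mvd up by 2.10 in the authors' deposited table. Uptake and sensing was lower at 6 of 11 in both counts (p 0.00352, adjusted 0.0133, Fisher's exact), including the receptor Lrp1 at -2.87 in the authors' deposited table. With calls at q under 0.01 these calls ended (adjusted Fisher's exact p 0.0659 and 0.105), as they did with a log2 fold change of at least 0.58 (0.0539 each). Export and lipoprotein genes were lower at 13 of 19, 15 over the list alone (Fisher's exact p 4.02e-07, adjusted 3.42e-06), with Abcg8 (-2.74) and Abcg5 (-2.22), which pair to export sterols, in the authors' deposited table. Bile acid genes were lower at 9 of 14, 10 over the list alone (p 5.77e-05, adjusted 0.000327, Fisher's exact), with Cyp7a1 at -3.34 in the authors' deposited table. Endothelial markers, higher in the knockout with DMSO, were lower after tunicamycin at 6 of 11 in both counts (median -0.73; Fisher's exact p 0.00352, adjusted 0.0133), such as Kdr (-0.87) and Clec4g (-1.04) of the authors' deposited table.

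Under tunicamycin the knockout had lower transcripts of the amino acid program and no called difference at the 15 tested ER chaperones. Asparagine synthetase Asns stood at 2.60 FPKM against 15.5 in wild type (log2 -2.57) and Psat1 at 12.5 against 61.5 (-2.30), in the authors' deposited table. The glutathione-degrading Chac1 (-2.10) and the glycine carrier Slc6a9 (-1.81) were lower too, while Ddit3 was at -0.21 and not called, per the authors' deposited table. Several bile acid genes were lower, and genes of adrenal gland and muscle were among the large rises. Both groups of this comparison ran on the same lane. Of 14919 tested loci 883 were called in the authors' deposited table, 556 higher and 327 lower, of which 443 and 91 were at least 2-fold, and 1551 had an unadjusted p under 0.05. With q within this comparison alone 557 calls were left, 169 of them lower, and Akr1cl, Slc1a5, Mlxipl and Gsta2 lost theirs.

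At 5 FPKM or more in the higher group, called falls were led by the host of Mir223 (-4.77), Asns, the glycosyltransferase Extl1 (-2.46), the elongase Elovl3 (-2.35), Psat1 and Kansl2, part of a histone acetyltransferase complex (-2.29), in the authors' deposited table. Rises by the same limit were led by Chgb (9.71), the steroid enzyme Cyp11a1 (9.52), the reductase Akr1cl (9.40), the Cyp11b1 and Cyp11b2 locus of corticosteroid synthesis (9.25), Chga (9.11) and Scg2 (8.33) in the authors' deposited table. These are genes of adrenal cortex, or, for Chgb, Chga and Scg2, of the secretory granules of adrenal medulla. Akr1b7 reached 332 FPKM, the steroid carrier Star 232 and Cyp11a1 138 in the knockout tunicamycin group of the authors' deposited table. The muscle genes Acta1 and Ckm reached 109 and 45.9 FPKM there against 1.21 and 0.507 in wild type with tunicamycin, and the fat gene Cfd 84.3 against 0.274, in the authors' deposited table. In lists written after these rises were seen, 5 of 12 genes of adrenal cortex, 3 of 9 of adrenal medulla, 8 of 15 of skeletal muscle and 2 of 8 of fat were higher. Without the 184 loci that stood 5 or more times above each other group, 782 calls were left, 455 higher and 327 lower.

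**Figure D1:**
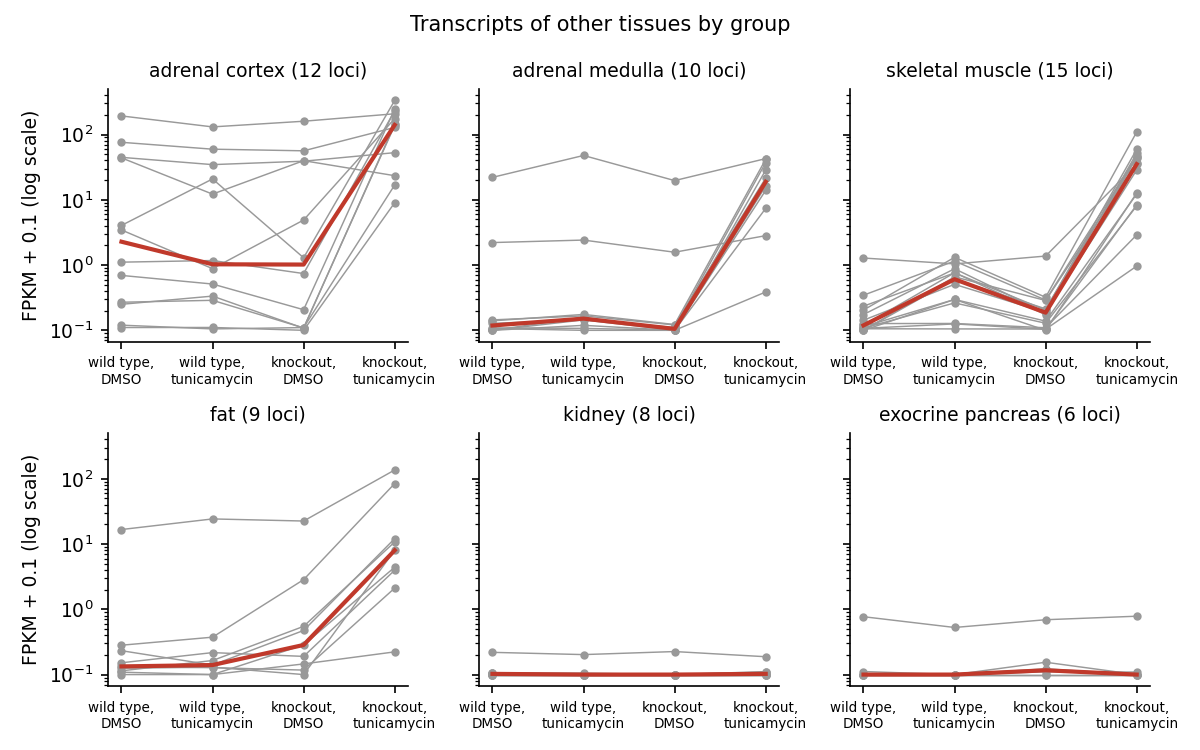
FPKM plus 0.1 (log scale) of marker genes of other tissues in the 4 groups, from the authors' deposited table. Grey lines are single loci and the thick red line is the median of the list, with 1 pooled value of 3 libraries per group.

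ATF4 and CHOP targets were lower at 12 of 23 and at 14 adjusted over the list alone (median -0.54; Fisher's exact p 2.34e-14, adjusted 1.59e-12). Besides Chac1 these included Fgf21 (-1.74), Nupr1 (-1.49), the mTOR inhibitor Ddit4 (-1.24) and the oxidase Ero1l (-1.07) of the authors' deposited table. Tnfrsf10b was the 1 higher member (2.75), and Trib3 (-0.50), Atf5 (-0.38) and Ddit3 were among those not called in the authors' deposited table. Amino acid synthesis was lower at 8 of 18, 10 over the list alone (median -0.59; Fisher's exact p 2.93e-09, adjusted 6.65e-08), with the mitochondrial folate enzyme Aldh1l2 at -3.28, Psph at -1.92 and Aldh18a1 at -1.91 in the authors' deposited table. Transporters were lower at 6 of 13, 8 over the list alone (median -0.56; Fisher's exact p 2.34e-07, adjusted 3.98e-06), such as Slc7a1 (-0.74) and Slc3a2 (-0.62), and the glutamine carrier Slc1a5 was higher (0.79) in the authors' deposited table. Cytosolic tRNA synthetases were lower at 6 of 20, 8 over the list alone (median -0.38; Fisher's exact p 4.6e-06, adjusted 6.26e-05), with Cars at -1.33 and Gars at -0.97 in the authors' deposited table.

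Cuffdiff called 0 of 15 ER chaperones, 0 of 18 genes of ER-associated degradation and 0 of 22 secretory genes, and 0 of each had an unadjusted p under 0.05. Their medians were -0.27, -0.26 and -0.15, at percentiles 3.05, 0.46 and 13.9 of random lists, so the first and second leaned lower as well, and whether they differ from the tRNA synthetases was not tested. Single values in the authors' deposited table were -0.40 for Creld2, -0.31 for Syvn1 and -0.36 for Dnajb9. Of the sensors and regulators 2 of 17 were lower, the merged Atf4 locus and IRE1, Ern1 (-0.59 in the authors' deposited table), which did not pass as a list (adjusted Fisher's exact p 0.286).

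**Figure D2:**
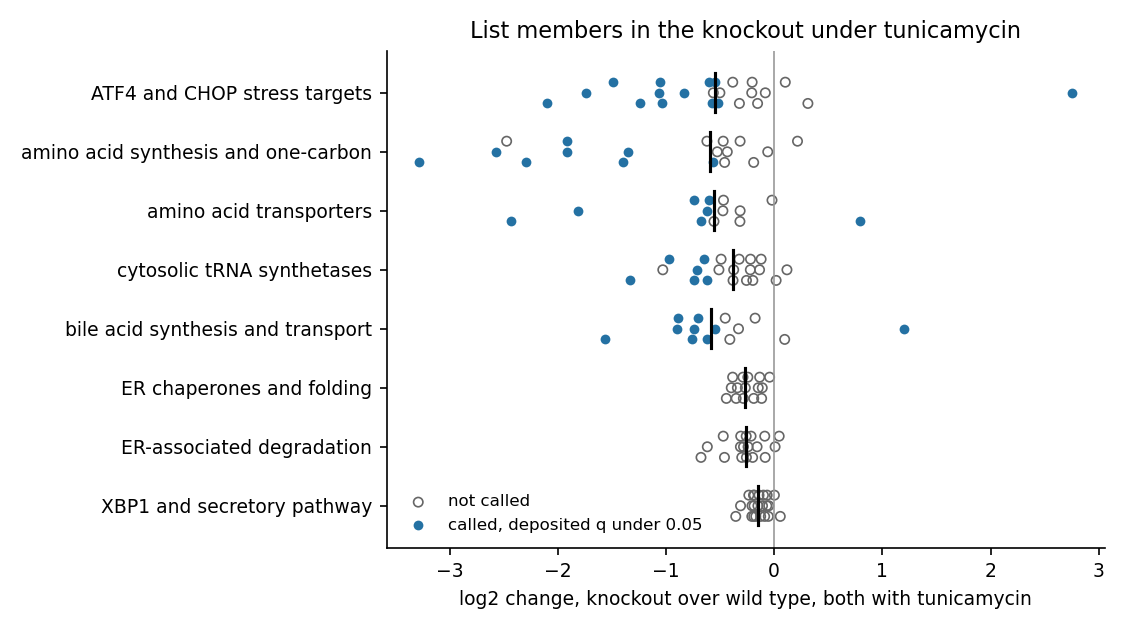
Log2 changes of list members, knockout over wild type, both with tunicamycin, from the authors' deposited table. Each point is a locus, filled if called (deposited q under 0.05), and black bars are list medians.

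Bile acid genes were lower at 8 of 14 in both counts (median -0.59; Fisher's exact p 2.19e-10, adjusted 7.43e-09) and at 3 with q within this comparison (Fisher's exact p 0.000612, adjusted 0.00693), among them Cyp39a1 (-1.56), Cyp8b1 (-0.89), the export pump Abcb11 (-0.70) and Cyp7a1 (-0.62), while the reductase Akr1d1 was higher (1.20), in the authors' deposited table. Few cholesterol genes were called. Biosynthesis had 1 higher and 1 lower of 19 (Dhcr7 1.31, Mvd -0.53), uptake 0 of 11 called by Cuffdiff with 3 at an unadjusted p under 0.05, and export 2 higher and 1 lower of 19, by the authors' deposited table. The higher ones were the HDL receptor Scarb1 (1.11), which is also an abundant adrenal transcript, and Apoa4 (0.61), and the lower one was hepatic lipase Lipc (-0.50), in the authors' deposited table. Against random lists the median of biosynthesis (0.04) stood at percentile 99.5 and that of export (-0.26) at 0.61.

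Fatty acid synthesis had 3 higher and 2 lower of 17 (adjusted Fisher's exact p 0.203 and 0.286), with Thrsp at -0.76 and the sugar-responsive regulator Mlxipl at -0.75 in the authors' deposited table. NRF2 and glutathione genes were lower at 4 of 17 in both counts (Fisher's exact p 0.000551, adjusted 0.00624): heme oxygenase Hmox1 (-0.77), Gsta2 (-0.76), Abcc4 (-0.66) and the cystine carrier Slc7a11 (-2.44) of the authors' deposited table. The median of that list was 0.04, and with loci of at least 1 FPKM, which leaves Slc7a11 out, its call ended (adjusted Fisher's exact p 0.0592). Cell death and p53 genes were higher at 4 of 13 in both counts (p 0.00145, adjusted 0.0141, Fisher's exact), namely Tnfrsf10b, Bax (1.05), Ccng1 (0.88) and Cdkn1a (0.62) of the authors' deposited table. Growth hormone genes had 3 lower and 1 higher of 20 (adjusted Fisher's exact p 0.0916 for falls, and 0.0154 with calls at q under 0.01), with Hsd3b5, a male-biased steroid enzyme, at -2.91 in the authors' deposited table.

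Both responses to tunicamycin were compared directly by a test of their difference, which is approximate and was computed from the authors' deposited table. It called 144 of 14510 loci, 91 with the knockout response above the wild-type response and 53 below, against 759 at an unadjusted p under 0.05. The knockout response is taken against the knockout DMSO group, the only group on its lane, so lane enters every one of these differences. It enters through the DMSO groups, and in that part it cannot be separated from genotype. The other part, knockout against wild type with tunicamycin, lies within 1 lane. The median standard error of a difference was 0.381 on the log2 scale, so most differences under 1 could not be told from 0. Of loci that rose in wild type, 70.8% had a smaller fold change in the knockout, and of loci that fell 77.2% did. These loci were picked by their wild-type call, which by itself favours smaller values in the other genotype.

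Among loci above in the knockout, Star (8.41), the transporter Abcb1b (7.11), the steroid reductase Akr1c18 (6.96), muscle troponins Tnnc2 (5.84) and Tnni2 (5.82) and Akr1b7 (5.72) had the largest differences of those with at least 5 FPKM in any group, computed from the authors' deposited table. Their adjusted p-values (normal, two-sided, on the authors' statistics) were 6.02e-16, 7.86e-32, 6.87e-16, 0.00371, 1.62e-05 and 2.66e-24. Lowest against wild type in that set were Hbb-b1 (-14.23), Slc22a27, an organic anion transporter named at several loci (-10.71), the predicted gene Gm5936 (-4.16), Cd97 (-3.87), Dancr with Snora26 (-3.55) and Serpina4-ps1 (-2.63), computed from the authors' deposited table. Their adjusted p-values (same test on the authors' statistics) were 0.000262, 1.85e-08, 0.00336, 1.28e-32, 5.13e-11 and 0.000334. Hbb-b1, Slc22a27 and Star were not called in either genotype alone by the deposited q, so their difference rests on the approximate standard error. With standard errors from the deposited p-values 48 loci were called and Cd97, Dancr, Abcb1b and Akr1c18 were the named ones left, and with the statistic not scaled 19 were called.

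Cd97 was called in opposite directions: it rose in wild type (q 0.000396), and in the knockout it fell from 29.9 to 8.19 FPKM (-1.87), in the authors' deposited table. The differences of Cd97, Dancr and Serpina4-ps1 rest in part on high values in the knockout DMSO group, where all 3 were called higher than in wild type in the authors' deposited table. Endothelial markers had a lower response in the knockout at 6 of 11, 10 adjusted over the list alone, with a median difference of -1.12. Amino acid synthesis was lower at 2 of 18, Aldh1l2 (-2.61) and Aldh18a1 (-2.20), and at 5 over the list alone, computed from the authors' deposited table. ATF4 and CHOP targets had 1 of 23 lower, Chac1 (-1.59), and 5 lower and 1 higher over the list alone, and transporters 1 of 12, Slc6a9 (-1.41), by the same computation from the authors' deposited table. The tRNA synthetases had 0 of 20 called, 3 over the list alone, and ER chaperones, ER-associated degradation and secretory genes 0 in both counts. Differences were below 0 at 13 of 15 chaperones (median -0.28), 13 of 18 degradation genes (-0.13) and 12 of 22 secretory genes (-0.04), computed from the authors' deposited table. The last 2 shares are near or below the 70.8% found over all loci that rose in wild type. Against random lists the 3 medians stood at percentiles 0, 0.24 and 3.33. Those lists were matched on mean FPKM and not on a rise in wild type. Knockout against wild type with DMSO, where lane and genotype cannot be told apart, had a chaperone median of 0.05 at percentile 100. That part lowers the chaperone differences. Thrsp (-1.22) and Hsd3b5 (-2.49) were lower and Scarb1 (1.54) and Akr1d1 (1.52) higher in the knockout response, computed from the authors' deposited table.

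**Figure D3:**
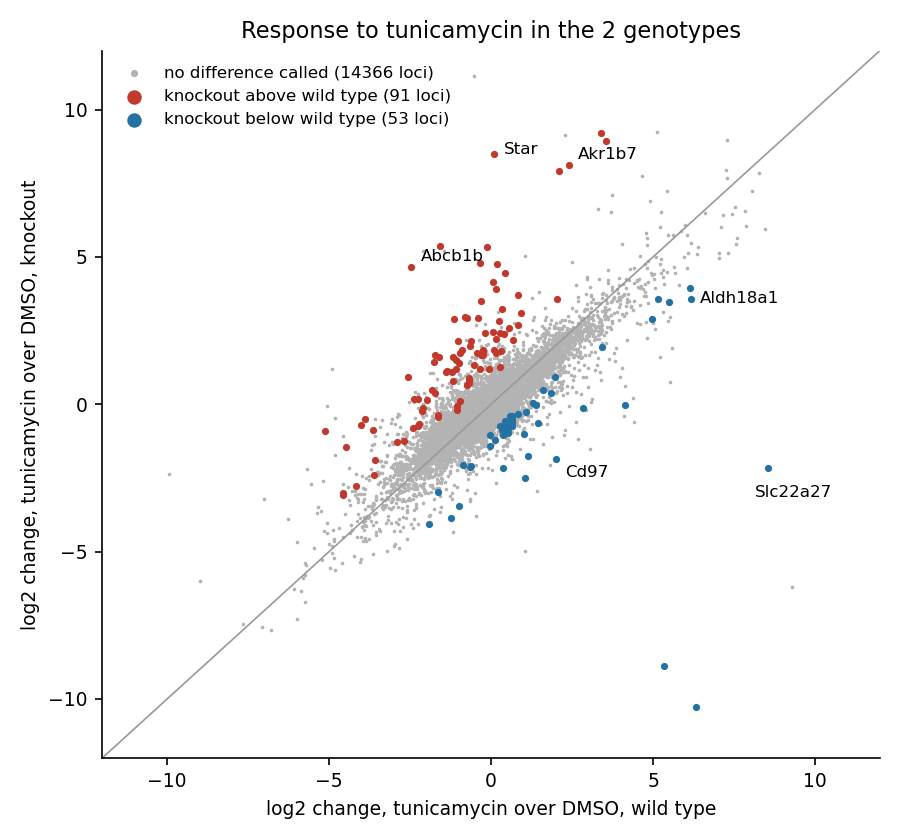
Log2 change with tunicamycin in the knockout against that in wild type, from the authors' deposited table. Each point is a locus with a test in both genotypes, coloured where the approximate test of the difference had an adjusted p under 0.05, and the line marks equal responses.

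The effects of the knockout without and with stress shared a small set of loci. Called in both and lower were the host of Mir223, Cyp3a16 and Extl1 (-2.56 with DMSO and -2.46 with tunicamycin for the last, in the authors' deposited table). Called in both and higher were Cdkn1a, Bax, Ccng1 and the p53 targets Zmat3 (1.33 and 1.43) and Aen (0.89 and 0.81), in the authors' deposited table. Of 13756 loci tested in both, 47 were higher in both against 4.85 expected (Fisher's exact test, two-sided, p 2.70e-33) and 35 lower in both against 4.43 expected (p 1.01e-21). At q under 0.01 in both, 21 and 10 were left. Opposite calls numbered 16 against 9.31 expected, such as Cd97 and Lyve1, higher with DMSO and lower with tunicamycin. Across 13744 loci the log2 changes had a Pearson r of 0.12 and a Spearman rho of 0.18, and loci are not independent replicates.

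Both tunicamycin responses shared most of their calls. Of 14584 loci tested in both genotypes 2121 were higher in both against 477 expected and 1951 lower in both against 440 expected, with 20 opposite. The correlation across 14510 loci was 0.84 (Pearson) and 0.86 (Spearman), where again loci are not independent replicates.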

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

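The tests of the first pattern, other-tissue RNA, and of the endothelial pattern after it were chosen only after those results were seen, while the test that raised the differences between genotypes had been fixed before. The responses to tunicamycin differed between wild type and knockout at 144 loci by the approximate test of the difference on the authors' deposited table, and a difference between groups is what raised the 12 loci with the largest values here.

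Transcripts of other organs were high in the knockout tunicamycin group, and 5 of the 6 largest positive differences (loci with at least 5 FPKM in any group) are of genes at home there: Star (8.41), Akr1c18 (6.96) and Akr1b7 (5.72) in adrenal cortex and the troponins Tnnc2 (5.84) and Tnni2 (5.82) in fast muscle, from the authors' deposited table. RNA of adrenal gland, muscle and fat in the samples fits: 37 further markers, picked once the pattern was known but before their own values were looked at, had a median log2 ratio of 2.28 to the highest other group after adding 0.1 FPKM to each value, and 31 were at least 2-fold above it, although only 17 reached 1 FPKM. The medians were 2.28 over 4 loci of adrenal cortex, 2.40 over 10 of medulla, 3.21 over 15 of muscle and 1.32 over 8 of fat (0.95 over the 3 fat loci that reached 1 FPKM), with kidney and exocrine pancreas at 0 and -0.01. Whether the rise was of similar size in all 3 knockout tunicamycin livers cannot be told from pooled values. Of loci rising at least 8-fold from between 0.1 and 1 FPKM with tunicamycin in the knockout, 8 of 11 markers failed the deposited test. Of other such loci that rose in wild type too, 5 of 29 failed (Fisher's exact test, two-sided, p 0.00174). By the same test, 2 earlier forms with other comparison loci or no lower bound gave p 0.00183 and 1.51e-05. These tests cannot decide the question: the markers had been seen and those of a tissue move together. In the last form the comparison loci were also picked for rising in wild type. Scaling of these libraries is excluded, with a median log2 change of -0.0527 over 12338 expressed loci, while values per library were not used here, so whether 1 or more libraries carry these transcripts is not known, and a change in liver cells of single genes was not tested.

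Endothelial markers were higher in the knockout with DMSO (median log2 0.73 over 11 loci in the authors' deposited table) and not with tunicamycin (median -0.34). A lower share of hepatocyte RNA as the whole cause would raise the markers of other cells alike, and the macrophage median was 0.02 over 13 loci. That median still stood at percentile 97.6 of random lists. A permutation test over loci (two-sided, p 0.00046) adds no separate evidence, since markers of a cell type move together and had been seen. Other medians were 0.35 for stellate cells, 0.32 for cholangiocytes, 0.50 for lymphocytes, 0.21 for neutrophils and 0.76 for erythroid cells. An effect of ATF4 loss that is alike with and without tunicamycin would need a rise under tunicamycin too, which these medians do not show, and the lower values of 11 of 11 markers there (exact sign-flip test, two-sided, p 0.000977) add no separate evidence, since the markers move together and had been seen. Lane or preparation batch cannot be told apart from genotype, because 0 knockout DMSO libraries shared a lane with another group. An effect of genotype that tunicamycin removes would raise the markers with DMSO as well. Either account alone would leave a median near 0 with tunicamycin, where both groups share a lane, against the -0.34 found. As a list those falls did not pass (adjusted Fisher's exact p 0.197). With tunicamycin in wild type, also within 1 lane, the median was 0.47 and 3 of 11 were higher (adjusted Fisher's exact p 0.679).

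The remaining differences are given as values computed from the authors' deposited table: Hbb-b1 -14.23 and Slc22a27 -10.71. Gm5936 was at -4.16, Dancr with Snora26 at -3.55 and Serpina4-ps1 at -2.63, computed from the authors' deposited table. Cd97 was at -3.87 and Abcb1b at 7.11, and both were called in each genotype alone in the authors' deposited table, in opposite directions. With DMSO and tunicamycin, Abcb1b read 1.20 and 0.218 FPKM in wild type and 0.327 and 8.19 in the knockout, in the authors' deposited table. It was thus highest in the group where transcripts of other organs were high, and whether it comes from them was not tested. Every difference uses the knockout DMSO group, and 0 of its libraries shared a lane with another group, so lane enters through the DMSO part. With tunicamycin, where both genotypes share a lane, knockout against wild type was 5.23 for Abcb1b and -1.87 for Cd97, both called in the authors' deposited table. For both, lane is not the whole cause. Dancr with Snora26 read 8.41 and 6.78 FPKM with tunicamycin in wild type and knockout, and 4.08 and 38.4 with DMSO, in the authors' deposited table. In the DMSO part of every difference lane cannot be told apart from genotype.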

How the results depend on the processing

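The alternatives that leave out loci specific to the knockout tunicamycin group, those with other standard errors and the list counts with q within each comparison were chosen only after the results were seen. Of the compared counts of calls, 90 stayed within 1.5 times and 41 moved, and the cause was not tested except where fewer loci were counted by construction. For knockout against wild type with DMSO, 423 calls became 170 (96 higher, 74 lower) at q under 0.01, 105 (58 and 47) at a log2 fold change of at least 1, 255 (80 higher) at 5 FPKM or more, and 105 (52 and 53) with q within the comparison. For tunicamycin, 5566 calls in wild type became 3372 (1676 and 1696) and 5121 in the knockout became 3007 (1713 and 1294) at a log2 fold change of at least 1. For knockout against wild type with tunicamycin, 883 calls became 557 (169 lower) both at q under 0.01 and with q within the comparison, and 534 (91 lower) at a log2 fold change of at least 1. There 387 (131 higher) were left at 5 FPKM or more and 328 higher at 1 FPKM or more. The difference between responses went from 144 to 90 (60 above, 30 below) at an adjusted p under 0.01, to 19 (16 and 3) with the statistic not scaled and to 48 (30 and 18) with standard errors from the deposited p. Of its 12 named loci, 4 kept their call with standard errors from the deposited p (Cd97, Dancr, Abcb1b and Akr1c18) and 6 with the statistic not scaled. Loci called alike in both knockout comparisons went to 31 (21 higher, 10 lower) at q under 0.01 and 24 (18 and 6) at a log2 fold change of at least 1 in both. Without the loci specific to the knockout tunicamycin group the list calls stayed at 8, 14, 19 and 7 in the 4 comparisons, and with q within each comparison they were 2, 17, 20 and 8. Of these, 3 of the 17 and 1 of the 20 passed by having 0 members called in that direction, fewer than other loci, so without them the tunicamycin counts stayed at 14 and 19. Over the alternatives tried on named genes 27 of their calls were lost. That none reversed is no evidence of stability. Other q-values, other standard errors and a pseudocount keep the sign of a change. Centring removed medians between -0.0919 and 0.0340, too small to reverse a named gene. Centring on spike-ins, leaving out libraries, another test tool and other splits of the libraries were not run, because only pooled group values without spike-in loci were used here, and for the same reason what depth limits cannot be stated.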

Other observations

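Of the tests in this part, those of the p53 targets were run on a list chosen only after p53 genes were seen among the rises, with genes not seen before and predictions written before the tests. The circadian clock list was lower after tunicamycin at 8 of 17 in both genotypes, which passed in the knockout (9 adjusted over the list alone; Fisher's exact p 0.00247, adjusted 0.0105) and not in wild type (8 over the list alone; adjusted 0.0553), where it passed with calls at q under 0.01 (adjusted 0.0132). The core activator Arntl (3.70), Nfil3 (2.65) and Per1 (1.76) were higher and Per3 (-3.15), Hlf (-2.97) and Dbp (-2.94) lower in wild type in the authors' deposited table. Hepatocyte transcription factors were lower at 8 of 14 in the knockout in both counts (Fisher's exact p 0.000477, adjusted 0.00232) and at 6 of 14 in wild type (7 over the list alone; adjusted 0.153), with the xenobiotic receptor Nr1i3 at -3.54 and Cebpa at -2.56 in wild type in the authors' deposited table. Of 16 autophagy genes 2 were higher in each genotype with tunicamycin, among them the cargo receptor Sqstm1 (2.07 in wild type and 2.14 in the knockout in the authors' deposited table). Of 22 ribosomal protein genes 1 was higher with tunicamycin in wild type and 4 in the knockout (0 and 2 over the list alone), against 4.30 and 4.38 expected. Their medians were 0.05 and 0.22. The knockout response minus the wild-type response was below 0 at 1 of 22 (median 0.25, percentile 98.6 of random lists), with 0 called. Knockout against wild type with DMSO, which enters it with lane, had a median of -0.27 at percentile 3.77.

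Xist, expressed from an inactive X chromosome, was between 58.1 and 67.2 FPKM in all 4 groups of the authors' deposited table, and the Y-linked Ddx3y, Eif2s3y, Kdm5d and Uty were at or near 0. Both beta and alpha globin would be expected from blood, yet Hbb-b1 read 1.45, 59.3, 135 and 0.286 FPKM where the merged Hba-a1 locus read 32.8, 27.6, 55.5 and 16.7 (wild type with DMSO and tunicamycin, then knockout with DMSO and tunicamycin) in the authors' deposited table. Reads of Hbb-b1 are shared with near-identical copies.

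Targets of p53 were higher in the knockout in both comparisons, and a hypothesis is that loss of ATF4 in liver raises p53 activity. Among 19 targets that had not been looked at, 8 of 18 tested were higher with tunicamycin, where both groups share a lane (Fisher's exact test, two-sided, p 2.18e-07, median log2 0.44), so the lane of the knockout DMSO libraries is not the whole cause. With DMSO 6 of 17 were higher (Fisher's exact p 1.53e-07, median 0.31). Of tested markers of other tissues, 0 of 8 of adrenal cortex, 0 of 2 of medulla and 0 of 1 of muscle were higher there. The fat gene Cfd was higher (0.182 to 2.75 FPKM, log2 3.92, in the authors' deposited table), 1 of 2 tested fat markers. RNA of adrenal gland and muscle is thus not the whole cause either, while RNA of fat was not excluded. Of the p53 targets, 2 of 17 with DMSO (Fisher's exact p 0.00197) and 8 of 18 with tunicamycin (1.37e-08) were left with q within each comparison. Separate causes in each comparison, a lane or batch with DMSO and other-tissue RNA with tunicamycin, were not excluded together, and 1 of the targets, Ak1, is also a muscle transcript (4.42 FPKM in the knockout with tunicamycin in the authors' deposited table). Tunicamycin itself lowered these targets, 11 of 17 in wild type (Fisher's exact p 0.0001) and 9 of 18 in the knockout (0.000765).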
